A study of Mus musculus with 12 samples.

How the data were processed

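Total RNA of mouse C57BL/6 embryonic stem cells was sequenced in 12 libraries of 4 groups with 3 libraries each. The groups were wild-type cells (WT), Mphosph8-null cells (MP8; the gene encodes the protein MPP8), Tasor-null cells (Tas) and Pphln1-null cells (Pph). MPP8, TASOR and periphilin are the core subunits of the human silencing hub (HUSH) complex. Libraries were grouped by the labels of the columns, and 0 per-sample columns were left without a library. The labels do not say whether the 3 libraries of a group came from separate clones or cultures, so the p-values measure only the spread between these libraries.

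The submitters' processing notes list FastQC, HISAT2 2.1.0, RSEM, DESeq 1.26.0 and the genome build GRCm39, without a role or an order. The 3 deposited tables each compared 1 null group with WT and listed 57180 genes with the same gene identifiers. Per the file headers, each library had a column of expected counts, the estimated number of reads per gene without normalization. Of the deposited estimated counts above 0, 32.5% were not whole numbers, with a tolerance of 1e-9. The authors also gave TPM, transcript levels scaled to a common total, per library. Per the file headers, each table also held the authors' fold change as a ratio of null over WT, the log2 of that fold change, and a p-value with its adjusted value. The WT values in the 3 tables differed by at most 0, so the WT libraries entered once. Symbols were taken from the tables. 525 listed genes had no symbol, and 230 symbols were shared by several listed genes.

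The expected counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr by group, libraries were scaled by TMM, and 1 robust quasi-likelihood fit of group means covered the 12 libraries with 8 residual degrees of freedom. It gave 6 comparisons over 16840 tested genes, 3 against WT and 3 between null genotypes. P-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05, and the same counts were made for changes of 2-fold or more. Levels are in CPM, counts scaled by the effective library size, given as mean ± SD of 3 libraries. Log2 fold changes are given ± SE of the fit. Library totals ranged from 17918770 to 21962079 estimated counts. A count of 0 was read as a level of up to 3 counts per library. The floors and fitted errors cover counting and library spread only, since the reads carried no molecular identifiers. Between libraries of the same group, the chi-square per degree of freedom over genes with at least 20 counts in a pair was 1.92 to 6.35, against 33.7 or more between groups. In simulated data built from these libraries, 200 genes were changed by known folds. For MP8 against WT, 71.6% of genes changed 1.5-fold, 79.1% changed 2-fold and 97.0% changed 4-fold were recovered among 16507 tested, with 11 false calls. For Tas the shares were 76.1%, 76.1% and 95.5% of 16486 tested genes with 8 false calls, and for Pph 76.1%, 79.1% and 95.5% of 16510 with 6.

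Before the data were examined, 27 gene lists, the tests and the rule for named genes were fixed. Lists with at least 3 tested members were tested by camera in limma 3.58.1, with a preset correlation of 0.01. Camera was run on the voom transform of the same counts and scaling, and Benjamini-Hochberg covered the 26 lists and 3 comparisons against WT together (78 tests), and separately the 78 tests between null genotypes. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list move 1 way on balance and does not compare the list with other genes. For each list, members were also counted with p-values adjusted over the list alone. The lists covered HUSH and its partners, naive and formative or primed pluripotency, the 2-cell-like state, germline and meiosis, primitive endoderm, mesendoderm, neuroectoderm, trophectoderm, feeder fibroblasts, clustered protocadherins, Zfp-named zinc finger genes, Hox, Rhox, and Mage and Xlr genes. The others were replication-dependent histones, the interferon response, p53 targets, the integrated stress response, imprinted genes, DNA methylation machinery, H3K9 and Polycomb modifiers, mitochondrially encoded genes, ribosomal proteins, the cell cycle, cholesterol synthesis, and glycolysis with hypoxia.

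Genes were named by a rule of 6 parts. These were the 3 lost genes with Setdb1, Morc2a and Atf7ip; per comparison with WT, the 10 largest rises and 8 largest falls with no overlap between libraries and a mean of at least 1 CPM; per list, up to 4 called members with the largest change; up to 10 genes per direction called in the 3 null genotypes; the 5 largest differences per direction between null genotypes; and uncalled members of called lists. Predicted gene models were left out of the ranked parts. Gene families were added after the data were examined, where the text says so.

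Calls common to the null genotypes were compared with independent lists. The correlation and covariance of log2 fold changes across genes, which are not independent replicates, were set beside 20 simulated draws of unchanged groups sharing 1 set of WT libraries. Protein-coding genes with 1 exon were compared with genes of several exons by Fisher's exact test, two-sided, and so were gene biotypes. Exon numbers, biotypes, gene spans and chromosomes came from the GENCODE annotation of GRCm38 and were matched by gene identifier alone for 97.9% of the tested genes; no coordinates are given, because the builds differ. Gene span was compared with 10000 draws of protein-coding genes matched by level.

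Alternatives fixed before the data were examined were DESeq2 size factors, library size alone, no filter, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, fits of 6 libraries, leaving out each library, the replicate number as a block, changes of 2-fold or more, and the estimated correlation. Leaving out chromosomes 8, 16 and 19, and the 2-fold limit for comparisons between null genotypes, the common genes, exon numbers and biotypes, were added after the data were examined. For chance, 10 splits of 6 libraries and 100 groupings of 12 libraries were refitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The authors' tests were used only for counts of their calls and of shared calls. Their 6 columns of group means were not used here, and TPM was used only for its sum over the listed genes.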

Results

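Gene expression was measured in mouse embryonic stem cells that lacked 1 of 3 subunits of the HUSH complex, a chromatin complex known to silence retroelements and other transcription units through methylation of histone H3 on lysine 9. The WT, MP8, Tas and Pph groups had 3 libraries each. Library totals ranged from 20392235 to 21962079 estimated counts in WT, from 17918770 to 20015735 in MP8, from 18898952 to 21112986 in Tas and from 17996836 to 19697066 in Pph. Between 22673 and 23609 genes had at least 1 count in a library, and 16840 genes were tested. The first 3 principal components held 41.1%, 23.8% and 16.1% of the variance, and the libraries of each group lay together on them. Spread within groups was small, with a common biological coefficient of variation of 0.0419.

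The transcript of the lost gene was lower in each null group. Mphosph8 (ENSMUSG00000079184) fell from 113 ± 3.23 CPM in WT to 0.306 ± 0.35 CPM in MP8 (0.705, 0.165 and 0.0494 CPM in the 3 libraries; log2 fold change -8.49 ± 0.15, which rests on MP8 replicate 1 since the others held 3 counts or fewer, edgeR adjusted p = 3.43e-18). Tasor (ENSMUSG00000040651) fell from 126 ± 2.7 to 31.9 ± 1.19 CPM in Tas (-1.99 ± 0.05, adjusted p = 8e-24), and Pphln1 (ENSMUSG00000036167) fell from 68.5 ± 2.91 to 21.3 ± 1.66 CPM in Pph (-1.69 ± 0.05, adjusted p = 1.54e-21). Transcripts of the other subunits changed too, by less. Tasor rose by 0.34 in MP8 and 0.56 in Pph on the log2 scale, reaching 186 ± 13.9 CPM in Pph, Pphln1 rose by 0.32 in MP8 and 0.13 in Tas, and Mphosph8 fell by 0.22 in Tas and 0.27 in Pph. Morc2a, a chromatin compactor recruited by HUSH, rose by 0.38 in MP8, 0.29 in Tas and 0.15 in Pph. Atf7ip, the partner of the methyltransferase SETDB1, rose by 0.38 in Tas, and Atf7ip2, its paralogue, rose in the 3 null groups, most in MP8 (1.21 ± 0.06). Setdb1 itself stood at 192 ± 2.98 CPM in WT, 189 ± 6.06 in MP8, 207 ± 2.39 in Tas and 181 ± 4.55 in Pph; its call in Pph, like those of Atf7ip in MP8 and Pphln1 in Tas, was lost under some settings. As a list, HUSH and its partners did not pass camera in any null group (adjusted p = 0.113 in MP8, 0.209 in Tas and 0.141 in Pph).

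**Figure D1:**
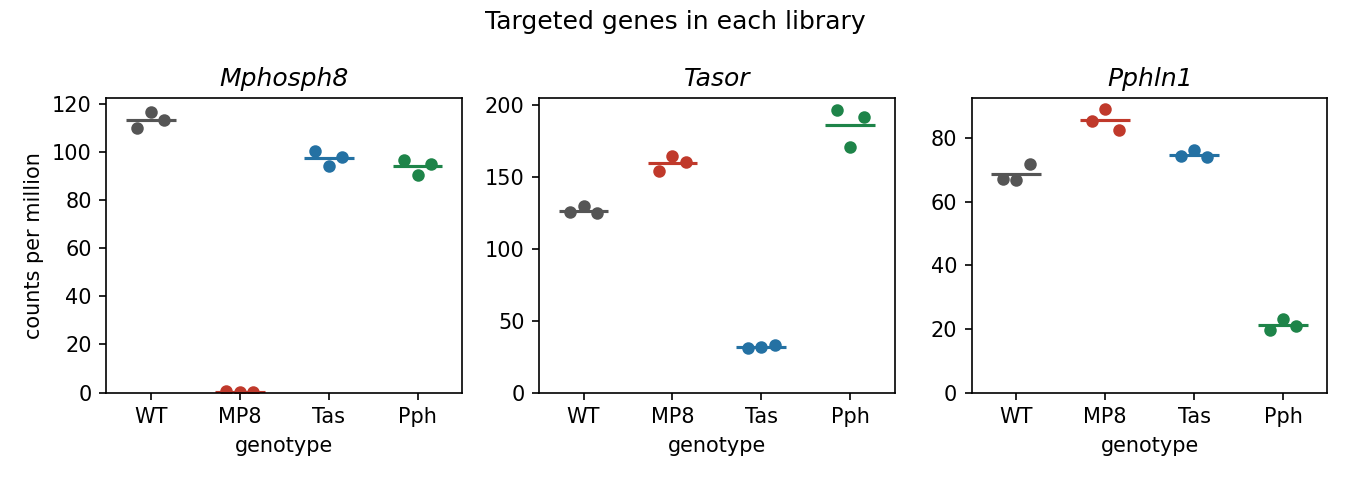
Level of Mphosph8, Tasor and Pphln1 in CPM for each library of the 4 groups (points; lines show the mean of 3 libraries). Each transcript was lowest in the group named for it, with a mean of 0.306 CPM for Mphosph8 in MP8, 31.9 CPM for Tasor in Tas and 21.3 CPM for Pphln1 in Pph.

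The comparison of MP8 with WT asked which transcripts depend on MPP8, the chromodomain subunit. Loss of Mphosph8 came with higher p53 targets, clustered protocadherins and Xlr genes, and lower genes of naive pluripotency, glycolysis and cholesterol synthesis. Among the largest rises, Cd36, a fatty acid transporter, rose from 1.85 to 68.3 CPM, Rhoj, a small GTPase of endothelial cells, from 0.757 ± 0.141 to 27.6 ± 1.91 CPM, and Taar7d, an odorant receptor of the trace amine family, from 0.204 ± 0.065 to 10.1 ± 0.62 CPM. The olfactory receptor genes Or2ak5 and Or14j6 were at no more than 1 and 2 counts in any WT library and reached 7.64 and 4.26 CPM in MP8, though reads of near-identical olfactory receptor copies are hard to assign. Falls beyond Mphosph8 included Gjb5, a gap junction protein (-3.60 ± 0.26), and Lrrc31 (-3.72 ± 0.23). In total 10477 genes were called, 5058 higher and 5419 lower, a balance that turned under other scalings; changes of 2-fold or more numbered 1677 higher and 737 lower. The 3 MP8 libraries lay entirely above or below the 3 WT libraries for 66.0% of genes, where chance gives 10%.

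Of 24 naive pluripotency genes, 17 fell and 5 rose in MP8 (camera adjusted p = 6.60e-05, 0.0240 with an estimated correlation), and the counts were the same when adjusted over the list alone. Klf4, a transcription factor of the naive state, fell from 35.2 ± 1.66 to 5.64 ± 0.294 CPM, and Tfcp2l1, another such factor, from 127 ± 8.81 to 21.7 ± 0.764 CPM. Dppa3, a maternal factor that protects imprints, fell by 2.27 on the log2 scale. Glycolysis and hypoxia genes fell for 22 of 24 members (adjusted p = 1.60e-12, 0.0240 with an estimated correlation), 22 of them also when adjusted over the list alone. Slc2a3, a glucose transporter, fell from 407 ± 13.1 to 69.6 ± 3.92 CPM, the phosphofructokinase Pfkp by 1.66 and the hypoxia-responsive mitophagy receptor Bnip3 by 1.60 on the log2 scale. Cholesterol synthesis genes fell for 19 of 21 members (adjusted p = 3.07e-07, 0.00841 with an estimated correlation; 19 lower and 1 higher adjusted over the list alone), with the sterol enzyme Msmo1 down by 0.89. P53 targets rose for 19 of 22 members (adjusted p = 1.23e-08, 0.00581 with an estimated correlation; 19 higher and 1 lower adjusted over the list alone). Ccng1, a p53-induced cyclin, rose from 191 ± 1.53 to 452 ± 17.2 CPM, Eda2r, a death receptor, from 34.3 ± 1.35 to 81.9 ± 3.43 CPM, and Cd80, a costimulatory ligand, from 1.74 ± 0.294 to 11.8 ± 0.673 CPM.

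Interferon response genes fell for 16 of 23 members in MP8 and rose for 2 (adjusted p = 0.00432, 0.0352 with an estimated correlation; 16 lower and 3 higher adjusted over the list alone), led by the antiviral gene Ifit2 (-2.84 ± 0.25). Cell cycle genes fell for 21 of 30 members and rose for 3, also adjusted over the list alone (adjusted p = 0.000131, 0.0492 with an estimated correlation). The D-type cyclin Ccnd3 fell by 1.10, the S-phase cyclin Ccne1 by 0.71, and Rb1, the retinoblastoma repressor of cell cycle entry, rose by 0.85. Clustered protocadherins, neuronal adhesion molecules, rose for 17 of 31 members with none lower, also adjusted over the list alone (adjusted p = 0.00100, 0.0216 with an estimated correlation). Pcdha6 rose from 0.372 ± 0.399 to 10.5 ± 0.506 CPM and Pcdhgb4 from 0.578 ± 0.369 to 4.4 ± 0.393 CPM, log2 fold changes of 4.82 and 2.93, or 5.96 and 3.54 without WT replicate 2; protocadherin genes of 1 cluster share exons, so their counts are uncertain. Mage and Xlr genes, X-linked families of the germline, rose for 14 of 26 members and fell for 3, also adjusted over the list alone (adjusted p = 0.00169, 0.0240 with an estimated correlation). Of the 9 tested Xlr genes 8 were called higher and 0 lower, so the list call rests largely on them and does not show a rise of Mage genes. Xlr3c rose from 0.556 ± 0.172 to 62.8 ± 2.02 CPM, with the limit that Xlr copies are near-identical. Zfp-named zinc finger genes, a class rich in KRAB repressors, rose for 191 of 395 members and fell for 56, also adjusted over the list alone (adjusted p = 4.69e-05, but 0.0889 with an estimated correlation). Zfp229 rose from 15.7 ± 0.28 to 89.7 ± 2.71 CPM and Zfp990 from 42 ± 2.07 to 164 ± 6.34 CPM.

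Several list calls of MP8 were lost with an estimated correlation. Fibroblast markers, included as signs of feeder cells, rose for 8 of 18 and fell for 2, also adjusted over the list alone (adjusted p = 0.0229, but 0.0776 with an estimated correlation and 0.0661 without chromosomes 8, 16 and 19). Ribosomal protein genes fell for 76 of 85 (adjusted p = 7.12e-11, but 0.290 with an estimated correlation), while Rpl10l, a germline retrocopy whose reads may be shared with its parent Rpl10, rose from 8.38 ± 0.738 to 61 ± 3.71 CPM. Mitochondrially encoded genes fell for 10 of 15 (adjusted p = 0.000321, but 0.178 with an estimated correlation), with the ribosomal RNA mt-Rnr2 down by 1.20. Replication-dependent histones fell for 16 of 33 (adjusted p = 0.0137, but 0.112 with an estimated correlation). Rhox genes, a homeobox family of the X chromosome, fell for 4 of 4 (adjusted p = 0.0137, but 0.156 with an estimated correlation), with Rhox6 down by 3.03. The lists for formative or primed pluripotency, germline and meiosis, primitive endoderm, mesendoderm, neuroectoderm, trophectoderm, Hox genes, the integrated stress response, imprinted genes, DNA methylation machinery, and H3K9 and Polycomb modifiers did not pass in MP8, with adjusted p between 0.0517 for DNA methylation machinery and 0.902 for trophectoderm. Single members of these lists were called. D1Pas1, a germline retrocopy whose reads may be shared with its parent Ddx3x, rose from 12.8 ± 0.414 to 102 ± 2.14 CPM, Sall2, a zinc finger gene of primed cells, by 1.75, and the imprinted antisense RNA Kcnq1ot1, which overlaps its host gene, by 1.68. The methylcytosine oxidase Tet2 fell by 1.34. Of the 2-cell-like list only 1 gene, Zfp750, was tested, so the list was not; Zfp750 rose by 0.71 in MP8 and 0.75 in Tas.

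Tas was compared with WT to ask which transcripts depend on TASOR, the scaffold of the complex. In Tas, formative and primed pluripotency genes, trophectoderm markers, cholesterol synthesis and interferon genes were lower, while p53 targets and Xlr genes were higher. Fgf5, a growth factor of formative cells, fell from 1.09 ± 0.224 to 0.0506 ± 0.00309 CPM, a level of 1 count per library. Prkg1, a cyclic GMP kinase, rose from 2.83 ± 0.475 to 70.1 ± 2.1 CPM, and Rhoj rose by 4.64 on the log2 scale. Xlr5c was at 1 count or fewer per WT library and reached 12.2 ± 0.679 CPM, uncertain among near-identical copies. Mid1, a ubiquitin ligase at the pseudoautosomal boundary, fell from 110 ± 2.93 to 5.85 ± 1.24 CPM, and the overlapping pseudoautosomal gene Erdr1y from 65 ± 9.98 to 1.78 ± 0.243 CPM; reads of Mid1 and the Erdr1 copies are hard to assign. Prune2 fell by 3.51 and Ankrd36 by 3.99. Exosc6, a subunit of the RNA exosome, had 0 counts in the 3 Tas and the 3 Pph libraries, a floor of 0.159 CPM or less in Tas and 0.167 CPM or less in Pph, against 4.21 CPM in WT. Its counts were uneven within groups, from 40 to 116 in WT and 19, 3 and 54 in the MP8 libraries. The call of Exosc6 in Tas and in Pph was lost under some settings, and why its counts varied was not tested. In total 8717 genes were called, 4415 higher and 4302 lower, a balance that also turned under other scalings, with 1110 higher and 610 lower by 2-fold or more. Libraries did not overlap for 58.1% of genes, where chance gives 10%.

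Formative and primed genes fell for 14 of 18 members in Tas and rose for 3 (camera adjusted p = 4.95e-05, 0.0183 with an estimated correlation; 14 lower and 4 higher adjusted over the list alone). Pou3f1, the POU factor OCT6, fell from 51.3 ± 5.95 to 11 ± 0.81 CPM, and Lef1, a Wnt pathway factor, from 11.9 ± 0.263 to 3.08 ± 0.308 CPM. Naive pluripotency genes moved both ways, 8 higher and 11 lower of 24, also adjusted over the list alone, and did not pass (adjusted p = 0.323). Klf4 fell by 2.92, while Nr5a2, a nuclear receptor that activates Pou5f1, rose from 43.8 ± 0.982 to 110 ± 1.15 CPM. Trophectoderm markers fell for 10 of 19 with none higher, also adjusted over the list alone (adjusted p = 0.00146, 0.0240 with an estimated correlation), among them the keratin Krt7 (-1.98 ± 0.19) and the transcription factor Tfap2c (-1.45 ± 0.07). Cholesterol synthesis genes fell for 19 of 21, also adjusted over the list alone (adjusted p = 5.47e-09, 0.00581 with an estimated correlation). Insig1, a sterol sensor, fell by 0.78. Interferon genes fell for 14 of 23 and rose for 3, also adjusted over the list alone (adjusted p = 0.00133, 0.0240 with an estimated correlation). Oasl2, an antiviral gene, fell from 6.95 ± 0.213 to 0.685 ± 0.146 CPM, and the immunoproteasome gene Psmb8 by 2.68.

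P53 targets rose for 16 of 22 in Tas with none lower, also adjusted over the list alone (adjusted p = 1.08e-05, 0.00841 with an estimated correlation), by less than in MP8: Ccng1 rose by 0.52, Eda2r by 0.87. Mage and Xlr genes rose for 13 of 26 and fell for 5, also adjusted over the list alone (adjusted p = 0.00576, 0.0373 with an estimated correlation). All 9 tested Xlr genes were called higher in Tas, so here too the list call rests largely on them. Germline and meiosis genes rose for 14 of 34 and fell for 3 (adjusted p = 0.0357, but 0.153 with an estimated correlation), D1Pas1 reaching 106 ± 1.4 CPM and Rpl10l 52.7 ± 2.82 CPM. Ribosomal protein genes fell for 48 of 85 (adjusted p = 4.90e-06, but 0.443 with an estimated correlation) and mitochondrially encoded genes for 9 of 15 (adjusted p = 4.69e-05, but 0.140 with an estimated correlation). Replication-dependent histones fell for 10 of 33 (adjusted p = 0.0366, but 0.155 with an estimated correlation, 0.0673 without WT replicate 1 and 0.0551 without Tas replicate 1). Rhox genes fell for 2 of 4 (adjusted p = 0.0341, but 0.224 with an estimated correlation). The other lists did not pass in Tas, with adjusted p between 0.130 for zinc finger genes and 0.907 for Hox genes. Within them the imprinted hydrolase Mest fell from 137 ± 4.18 to 26.6 ± 1.11 CPM, the chromatin remodeller Hells rose from 375 ± 10.3 to 665 ± 12.4 CPM, and the methyltransferase Dnmt3b fell by 0.76. By chromosome, an analysis of genes with a mean of at least 5 CPM that was chosen after the data were examined, genes of chromosome 19 were higher in Tas with a median log2 fold change of 0.26 and 85.2% of genes above 0 (camera with an estimated correlation, adjusted p = 0.000118). Genes of chromosome 8 had a median of 0.34 with 72.8% above 0 (adjusted p = 0.00764).

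The question for Pph was which transcripts depend on periphilin, the RNA-binding subunit. Pph showed higher trophectoderm, fibroblast and stress response genes together with lower naive and formative pluripotency genes. The keratin genes Krt8 and Krt18 of simple epithelia rose by 3.21 ± 0.04 to 440 CPM and by 3.16 ± 0.04 to 292 CPM, from 47.6 ± 1.73 and 32.8 ± 0.554 CPM in WT. Hand1, a factor of trophoblast giant cells and mesoderm, rose from 3.12 ± 0.44 to 34.7 ± 2.24 CPM, and Igf2, an imprinted growth factor, from 34.2 ± 1.8 to 281 ± 1 CPM. Other large rises were Csf1, the macrophage growth factor (4.33 ± 0.16), and Loxl4, a collagen crosslinking enzyme (3.62 ± 0.14). Gstp2, a glutathione transferase, fell from 20.3 ± 0.725 to 1.45 ± 0.0237 CPM, Inhbb, an activin subunit, from 4.45 ± 0.195 to 0.257 ± 0.0414 CPM, and Ankrd36 by 5.01. In total 9482 genes were called, 5151 higher and 4331 lower, with 1500 higher and 377 lower by 2-fold or more. Libraries did not overlap for 60.3% of genes, where chance gives 10%.

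**Figure D2:**
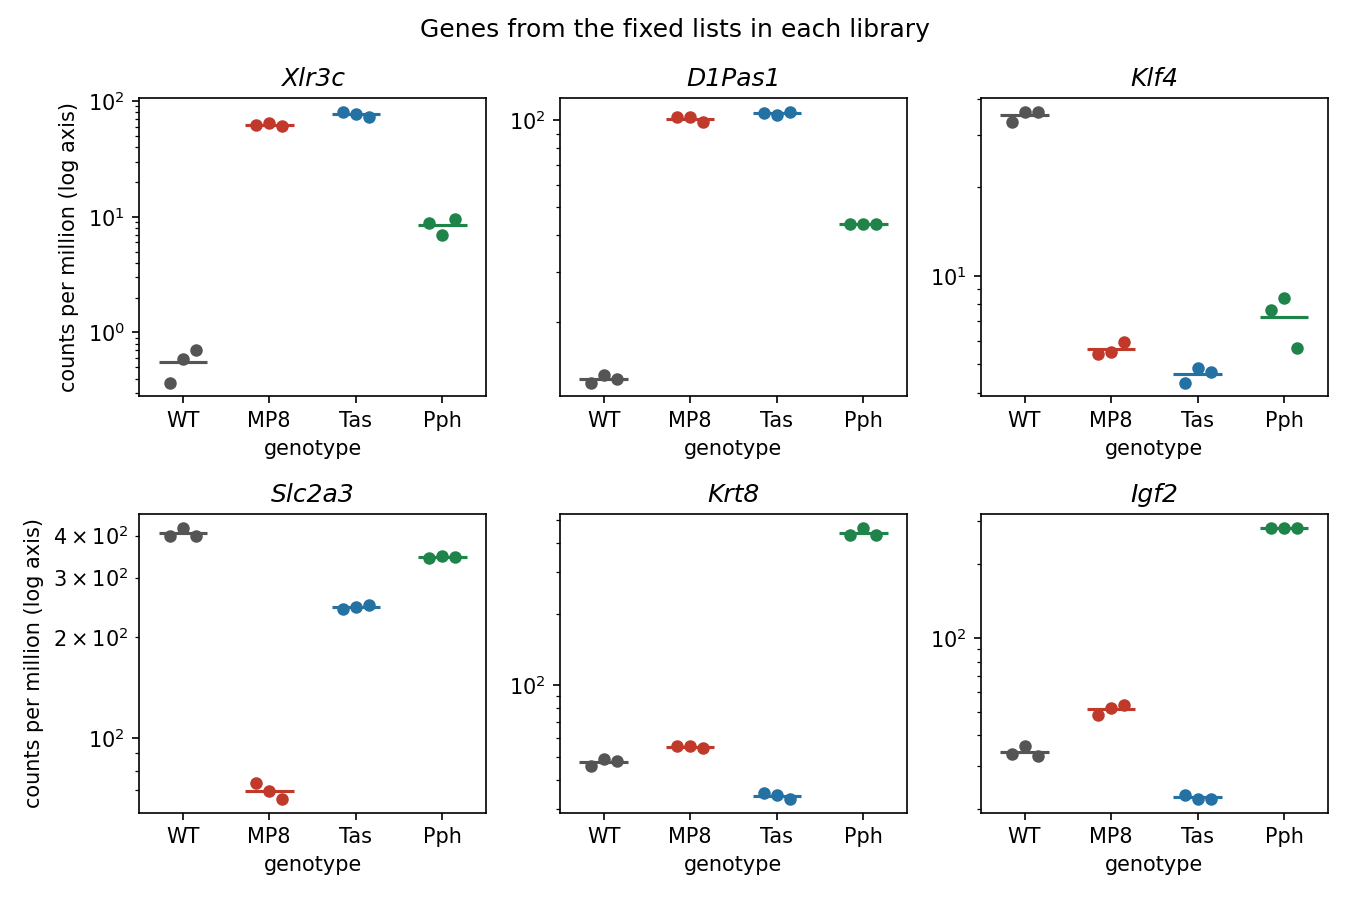
Level in CPM, on a log axis, of 6 genes from the fixed lists, Xlr3c, D1Pas1, Klf4, Slc2a3, Krt8 and Igf2, in each of the 12 libraries (points by group; lines show the mean). Krt8 and Igf2 averaged 440 and 281 CPM in Pph, Slc2a3 69.6 CPM in MP8 against 407 CPM in WT, and Klf4 was lower in the 3 null groups than in WT.

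Trophectoderm markers rose for 15 of 19 in Pph and fell for 1, Tfap2c, also adjusted over the list alone (camera adjusted p = 5.61e-07, 0.00581 with an estimated correlation). Tfap2c fell from 37.9 ± 1.45 to 20.1 ± 0.241 CPM. Members not called included Eomes, at 6.12 ± 0.0303 CPM in WT and 5.6 ± 0.923 in Pph, and Tfap2a, at 0.633 ± 0.274 and 0.55 ± 0.147 CPM. The listed Elf5, Tpbpa, Prl3d1 and Prl2c2, named after their values were seen, were too low to be tested. Cdx2, the trophectoderm master factor, stayed low at 2.31 ± 0.597 CPM after 0.254 ± 0.0578 CPM in WT. Fibroblast markers rose for 16 of 18 and fell for 1, also adjusted over the list alone (adjusted p = 3.07e-07, 0.00581 with an estimated correlation). The member that fell was Fn1, fibronectin, from 1206 to 1068 CPM, named after its values were seen. Tagln and Acta2, actin-associated genes of contractile cells, rose from 14.7 ± 0.156 to 116 ± 3.94 CPM and from 2.46 ± 0.347 to 15.3 ± 1.88 CPM, and the collagen Col3a1 from 0.479 ± 0.191 to 5.6 ± 0.725 CPM. Primitive endoderm genes rose for 10 of 15 with none lower, also adjusted over the list alone (adjusted p = 9.61e-05, 0.0468 with an estimated correlation), led by the basement membrane collagens Col4a2 (2.74 ± 0.06) and Col4a1 (2.03 ± 0.05). Integrated stress response genes rose for 17 of 20 and fell for 1 (adjusted p = 8.22e-07, 0.0191 with an estimated correlation; 18 higher and 1 lower adjusted over the list alone). Chac1, which degrades glutathione, rose from 3.57 ± 0.389 to 18.2 ± 0.603 CPM, and the stress factors Atf3 and Ddit3 rose by 1.94 and 1.65. P53 targets rose for 18 of 22 and fell for 2, also adjusted over the list alone (adjusted p = 2.78e-05, 0.00976 with an estimated correlation), with Perp, an epithelial adhesion gene, up by 1.34 and the kinase Plk2 by 1.32. Imprinted genes rose for 20 of 38 and fell for 7 (adjusted p = 0.00988, 0.0496 with an estimated correlation; 21 higher and 8 lower adjusted over the list alone), and Peg10, a retrotransposon-derived placental gene, rose from 450 ± 25.5 to 921 ± 14.1 CPM. Clustered protocadherins rose for 19 of 31 and fell for 2 (adjusted p = 0.0137, 0.0496 with an estimated correlation; 20 higher and 2 lower adjusted over the list alone).

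Naive pluripotency genes fell for 21 of 24 in Pph and rose for 2 (adjusted p = 3.23e-12, 0.00581 with an estimated correlation; 22 lower and 2 higher adjusted over the list alone). Klf4 fell by 2.28, Tcl1, a kinase coactivator, by 2.06, and Tbx3, a T-box factor, from 8.13 ± 0.791 to 2.03 ± 0.189 CPM. Formative and primed genes fell for 13 of 18 and rose for 4 (adjusted p = 0.000124, 0.0196 with an estimated correlation; 14 lower and 4 higher adjusted over the list alone), and the homeobox factor Otx2 fell from 16.4 ± 0.298 to 1.55 ± 0.178 CPM. Further calls were lost with an estimated correlation. Ribosomal protein genes fell for 83 of 85 (adjusted p = 5.18e-26, but 0.118 with an estimated correlation), mitochondrially encoded genes for 10 of 15 (9.61e-05, but adjusted p = 0.153 with an estimated correlation) and Rhox genes for 4 of 4 (0.00568, but adjusted p = 0.132 with an estimated correlation). Replication-dependent histones fell for 14 of 33 (adjusted p = 0.00691, but 0.0889 with an estimated correlation). Cell cycle genes fell for 17 of 30 and rose for 6 (adjusted p = 0.00317, but 0.102 with an estimated correlation). Cholesterol synthesis genes fell for 10 of 21 and rose for 4 (adjusted p = 0.0257, but 0.112 with an estimated correlation). Glycolysis and hypoxia genes fell for 13 of 24 and rose for 5 (adjusted p = 0.0239, but 0.347 with an estimated correlation), while Vegfa, an angiogenic factor, rose from 13.9 ± 1.72 to 45.7 ± 3.14 CPM. Interferon genes fell for 11 of 23 and rose for 2 (adjusted p = 0.0176, but 0.0624 with an estimated correlation and 0.0545 without chromosomes 8, 16 and 19). Mage and Xlr genes, with 12 of 26 higher and 4 lower, did not pass (adjusted p = 0.0570), although Xlr3c rose from 0.556 ± 0.172 to 8.44 ± 1.36 CPM. The remaining lists did not pass in Pph, with adjusted p between 0.0506 for DNA methylation machinery and 0.902 for germline and meiosis.

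**Figure D3:**
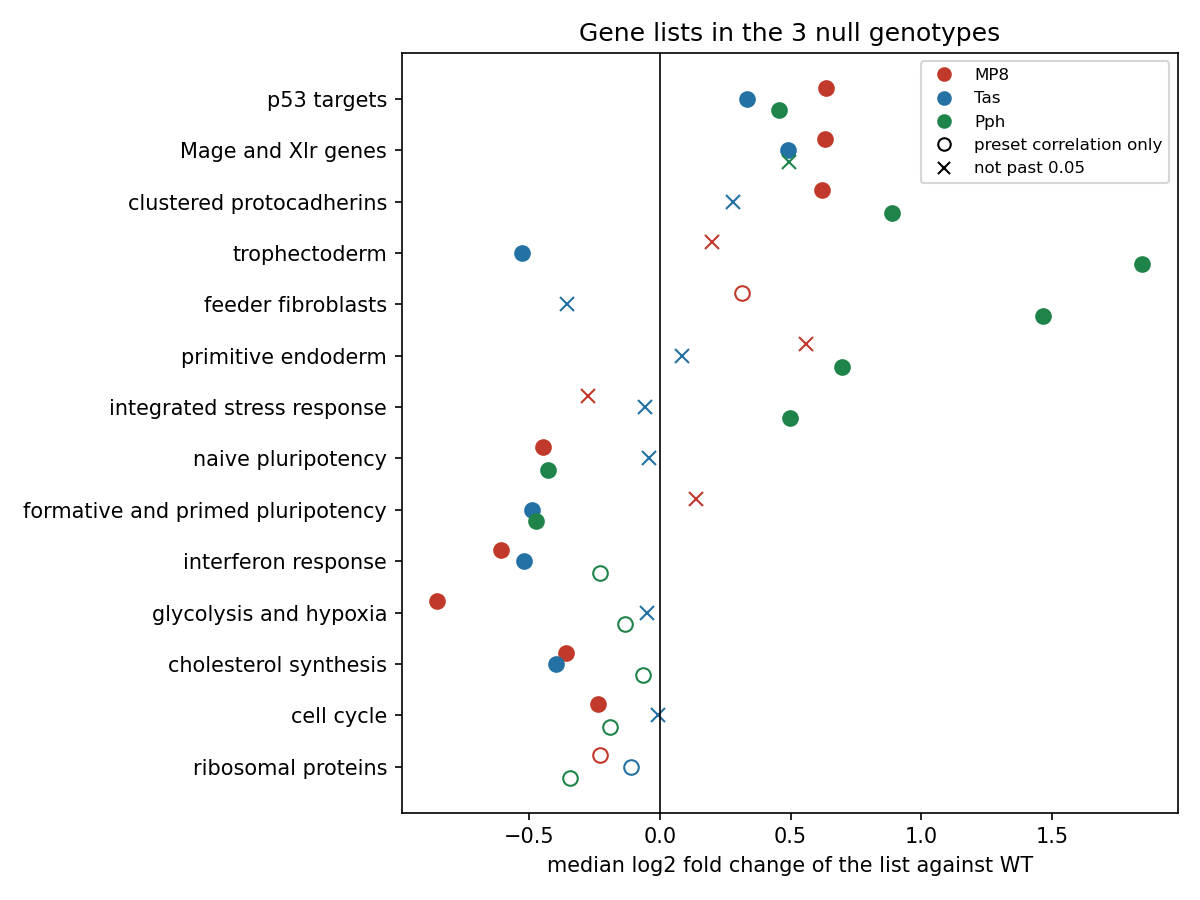
Median log2 fold change against WT of the tested members of 14 fixed gene lists in MP8, Tas and Pph, with higher levels right of 0. Filled circles mark an adjusted camera p under 0.05 with both the preset and the estimated correlation, open circles with the preset correlation only, and crosses neither. The median for trophectoderm markers was 1.85 in Pph and -0.53 in Tas, and for glycolysis and hypoxia genes it was -0.85 in MP8.

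Genes called in 1 direction after loss of each subunit were counted to ask what the null genotypes shared. Of the 596 genes that rose 2-fold or more in all 3, 504 rose most in MP8. Rhoj rose by 5.17 in MP8, 4.64 in Tas and 3.38 in Pph, and Nalf1, a subunit of a sodium leak channel, by 4.83, 4.08 and 3.36. Cylc1, a sperm head protein, was at 6 counts or fewer per WT library and averaged 4.42 CPM in MP8, 2.38 in Tas and 2.01 in Pph. Epha6, an ephrin receptor, and Plcl1, a phospholipase-like protein, rose in the 3 null groups too. The summed level of Xlr genes, a family total chosen after the data were examined and less affected by reads shared within the family, was 6.55 ± 0.521 CPM in WT, 208 ± 3.14 in MP8, 225 ± 7.28 in Tas and 41.4 ± 2.58 in Pph. Shared falls included Klf4, Esp4, a secreted peptide (-3.10, -2.75 and -3.50), and Mcc, a regulator of Wnt signalling, from 93.5 ± 4.86 CPM in WT to 20.8 ± 0.831, 24.2 ± 1.09 and 18.4 ± 0.928 CPM. In all, 3246 genes were called in 1 direction in the 3 null genotypes, 1787 higher and 1459 lower, where independent lists would share 762, a value that does not allow for the shared WT libraries. Simulated unchanged groups sharing WT libraries gave at most 1 such gene in 20 draws. These draws held only the spread between libraries of a group. A difference between the WT cells or culture and all null cells was not simulated and could also give shared calls. By 2-fold or more, 596 rose and 67 fell in all 3, and of these 663 genes 408 also differed 2-fold or more between null genotypes (61.5%, against 26.1% of other genes of like level). The choice of genes with large changes favours this difference, and matching by level does not remove it. Of the 596, 47.5% had a mean below 1 CPM in WT, against 16.1% of all tested genes, a share that the filter and the choice of rising genes favour. Among the 596, the median log2 fold change was 3.47 in MP8, 2.92 in Tas and 2.25 in Pph. The 3 comparisons share the same WT libraries.

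Across 16840 genes, which are not independent replicates, log2 fold changes of MP8 and Tas had a Pearson correlation of 0.68, a Spearman correlation of 0.46 and a covariance of 0.548. For MP8 and Pph the values were 0.66, 0.51 and 0.487, and for Tas and Pph 0.53, 0.34 and 0.337. Simulated unchanged groups against the same kind of shared WT libraries gave covariances of 0.0257, 0.0258 and 0.0259 for these pairs but correlations of 0.48, 0.49 and 0.49. The share of genes with the same sign was 66.9%, 68.5% and 62.5%, against 66.2%, 66.2% and 66.3% in the simulated groups. The simulated groups held no changed genes, so noise of the shared WT libraries set their correlations and shares of signs. In the real data many genes were called, and the simulated covariances were far smaller than those found. The simulated shares therefore cannot decide how far the null genotypes agreed in sign. A difference of the WT cells or culture from all null cells was not simulated. Without WT replicate 2, where 17197 genes were tested, the covariances were 0.639, 0.575 and 0.416.

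Null genotypes were also compared directly, without the WT libraries. Trophectoderm markers were lower in Tas than in Pph for 17 of 19 members with none higher (camera adjusted p = 1.30e-09, 0.0110 with an estimated correlation) and lower in MP8 than in Pph for 15 of 19 with 1 higher (adjusted p = 2.68e-07, 0.0110 with an estimated correlation). Glycolysis and hypoxia genes were lower in MP8 than in Tas for 22 of 24 and lower than in Pph for 24 of 24 (adjusted p = 1.13e-13 for both, 0.0223 with an estimated correlation for both). Naive pluripotency genes were lower in MP8 than in Tas for 16 of 24 and higher for 4 (adjusted p = 8.77e-05, 0.0223 with an estimated correlation), and higher in Tas than in Pph for 18 with 3 lower (adjusted p = 2.18e-06, 0.0198 with an estimated correlation). Formative and primed genes were higher in MP8 than in Tas for 14 of 18 with 3 lower (adjusted p = 5.49e-05, 0.0198 with an estimated correlation). Integrated stress response genes were lower in MP8 than in Pph for 15 of 20 with none higher (adjusted p = 3.22e-07, 0.0198 with an estimated correlation). P53 targets were higher in MP8 than in Tas for 15 of 22 with 1 lower (adjusted p = 5.49e-05, 0.0198 with an estimated correlation). Among single genes, S100a6, a calcium-binding protein, was at 62.7 ± 0.25 CPM in Pph and 4.57 ± 0.901 in MP8, and Hydin, a protein of motile cilia, at 30.3 ± 1.01 CPM in Tas and 0.969 ± 0.277 in Pph. Fat4, an atypical cadherin, was at 2.55 ± 0.548 CPM in MP8 and 0.0666 ± 0.0736 in Tas. Between MP8 and Tas 9447 genes differed, between MP8 and Pph 9908, and between Tas and Pph 9736, of which 1766, 2149 and 2062 differed by 2-fold or more.

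Because HUSH is known to act on intronless transcription units, protein-coding genes with 1 exon were compared with those of several exons. Among 360 genes with 1 exon, 28.9% were called higher in MP8, 20.6% in Tas and 26.4% in Pph, against 28.3%, 24.8% and 30.8% of 14006 genes with several exons (odds ratios 1.03, 0.786 and 0.807; Fisher's exact test, adjusted p = 0.813, 0.0965 and 0.0988). Genes with 1 exon were called lower less often (odds ratios 0.673, 0.761 and 0.751, adjusted p = 0.00163, 0.0436 and 0.0410), a difference that was lost among genes with a mean of at least 5 CPM (odds ratios 0.970, 0.974 and 1.16). For rises of 2-fold or more, a limit chosen after the data were examined, the odds ratios were 2.04, 2.33 and 2.05 (adjusted p = 0.000141, 0.000142 and 0.000141). Falls of 2-fold or more also had odds ratios over 1, of 1.30, 2.62 and 3.08 (adjusted p = 0.263, 6.85e-05 and 0.000141). Among biotypes, lncRNA genes were called higher at any fold for 40.1% in MP8, 35.4% in Tas and 29.5% in Pph, against 29.1%, 25.4% and 30.7% of other genes (Fisher's exact test, adjusted p = 2.93e-14, 5.87e-13 and 0.405). Pseudogenes were called higher for 42.0%, 37.7% and 34.6%, against 29.4%, 25.6% and 30.5% of other genes (adjusted p = 1.73e-10, 2.33e-10 and 0.0449). Among genes with a mean of at least 5 CPM 66.4%, 69.2% and 58.5% of lncRNA genes were called higher, against 30.9%, 29.5% and 32.0% of other genes, and 53.4%, 56.4% and 52.5% of pseudogenes, against 31.4%, 30.0% and 32.3% (largest adjusted p = 9.03e-09), so the result for lncRNA genes in Pph depended on the filter. The mean of at least 5 CPM was taken over the 12 libraries, most of them from null groups. It therefore favours low genes that rose in the null groups, which can raise the shares called higher under this filter. Without that filter, lncRNA genes and pseudogenes were called lower less often than other genes (odds ratios 0.237, 0.216 and 0.375 for lncRNA genes and 0.299, 0.169 and 0.435 for pseudogenes, largest adjusted p = 6.70e-14). With the limit of 2-fold, 28.0% of lncRNA genes rose 2-fold or more in MP8, 21.2% in Tas and 16.2% in Pph, and 32.9%, 25.4% and 21.9% of pseudogenes did, against 6.86%, 4.01% and 7.47% of protein-coding genes (Fisher's exact test of each biotype against all other genes, largest adjusted p = 1.86e-16). The main filter also admits genes that are low in WT and pass through a null group alone, which can raise the shares of rises in classes of low genes. Falls of 2-fold or more were found for 4.95%, 3.74% and 4.95% of lncRNA genes, against 4.28%, 3.60% and 1.95% of other genes (adjusted p = 0.339, 0.829 and 6.76e-09), and for 3.46%, 1.81% and 2.80% of pseudogenes, against 4.36%, 3.68% and 2.13% (adjusted p = 0.404, 0.0187 and 0.305), where the odds ratio in Tas went from 0.483 to 1.46 with at least 5 CPM and the call was lost (adjusted p = 0.409).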

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

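The tests of the trophectoderm and fibroblast genes and of the sum of TPM were chosen only after the results were seen, while the splits and groupings of the libraries were fixed before. Genes that moved in opposite directions in a pair of null genotypes numbered 1324 for MP8 and Tas, 1245 for MP8 and Pph, and 1575 for Tas and Pph. Each of these genes also differed in the direct comparison, which opposite calls in the same fit make nearly certain. The counts were below the 2713, 2958 and 2451 of independent lists, which do not allow for the shared WT libraries. By 2-fold or more in each, 65, 38 and 65 genes did so, among them Hydin, a protein of motile cilia, which rose by 3.49 in Tas and fell by 1.47 in Pph, and Aldh3a1, an aldehyde dehydrogenase, which rose by 1.20 in Tas and fell by 2.46 in MP8 on the log2 scale.

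Trophectoderm markers fell in Tas and rose in Pph, and the direct comparison of Tas with Pph gave a camera adjusted p of 1.30e-09. Fibroblasts of a feeder layer bring collagens rather than keratins. The keratins Krt8 and Krt18 rose by 652 CPM in Pph and the collagens Col1a1, Col1a2 and Col3a1 by 26.4 CPM, a ratio of 24.7. These values argue against such fibroblasts as the source of the rise of these keratins. For the rise of the fibroblast list itself, 5 of the 22 listed genes averaged under 1 CPM in Pph and the rest averaged 1 CPM or more. Among the 5 were Postn, Lum and Prrx1, near the floor at 0.0519, 0.0529 and 0.135 CPM. The count rests on levels and not on rises. Members such as Fn1 stood far above 1 CPM in WT already (1206 CPM), so the count cannot decide. A small share of fibroblasts is thus not told apart from expression of these genes by the stem cells or their differentiated progeny. A candidate explanation is partial differentiation of Pph cells, in all cells or in a few, which bulk libraries do not separate, and whether it follows from the loss of Pphln1 or from the culture was not tested.

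The listed genes did not sum to the full scale of TPM, and the part not carried by the genes listed in the tables used here was larger in each null group than in WT. It was 3.97% in MP8, 2.83% in Tas and 1.95% in Pph, against 1.04 ± 0.196% in WT, with no overlap of libraries.

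Other splits of the libraries tested whether chance groupings give results as large. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of the 6 comparisons 1 split, the real one, gave as many genes: 10477 for MP8, 8717 for Tas and 9482 for Pph against WT, and 9447, 9908 and 9736 between null genotypes, with at most 0, 1, 0, 0, 0 and 0 genes in the other splits. Of 100 groupings of the 12 libraries, 1, the real one, gave as many genes called in 1 direction in all 3 (3246, highest other 843). The same held for the covariances of MP8 and Tas (0.548, highest other 0.329), MP8 and Pph (0.487, highest other 0.376) and Tas and Pph (0.337, highest other 0.322), again with 1 of 100. Random labels of these libraries thus gave no count or covariance as large. Libraries of the same group lay close together, so groupings that mixed groups could hardly give as many genes. The groupings therefore cannot speak to differences between clones or cultures. For the number of gene lists past the threshold, 42, 6 of the 100 groupings gave as many, with up to 50. Groupings that mix genotypes can still carry differences between genotypes, which camera can detect. This share is therefore no measure of chance for the lists, and chance is not excluded by it.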

How the results depend on the processing

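Leaving out chromosomes 8, 16 and 19 was chosen after the data were seen, and so was the 2-fold limit for comparisons between null genotypes, for genes common to the 3, for exon numbers and for biotypes; the other alternatives were planned. Counts of called genes stayed within 1.5 times their values under other scalings, filters, tests, fits and left-out libraries, except under the 2-fold limit, which by construction leaves fewer genes: 2414 in MP8, 1720 in Tas, 1877 in Pph, 1766, 2149 and 2062 between null genotypes, and 663 in all 3. The balance of directions depended on the scaling, and most called changes were below 2-fold. By library size alone, 5521 genes were higher and 4907 lower in MP8, 4214 and 4601 in Tas, and 5801 and 3714 in Pph, and with DESeq2 size factors 5243 and 5238 in MP8 and 4351 and 4399 in Tas. The majority turned in MP8 and Tas, and between null genotypes it turned under at least 1 alternative in each comparison, but not in Pph or among the genes common to the 3. In Pph the balance was close with the DESeq2 test (4222 higher and 4151 lower). The authors' deposited calls for Pph turned it, with 3615 higher and 3896 lower. With each library left out in turn, the counts ranged from 9771 to 10660 for MP8, from 7833 to 8922 for Tas, from 8742 to 9502 for Pph, and from 2846 to 3291 for all 3. Covariances fell to 0.438, 0.352 and 0.258 for MP8 with Tas, MP8 with Pph and Tas with Pph among genes with a mean of at least 5 CPM, where the low-count genes are removed. Leaving out libraries gave 0.563 to 0.639, 0.499 to 0.575 and 0.345 to 0.416, highest without WT replicate 2. Each fit without a library gave higher covariances than the fit of 12 libraries. Those fits also tested more genes (17159 to 17302 against 16840), as the filter then admits more low-count genes. What set WT replicate 2 apart was not tested. Lower calls of genes with 1 exon had odds ratios of 0.970 in MP8, 0.974 in Tas and 1.16 in Pph with at least 5 CPM, where fewer genes are tested, so the call was lost in MP8 and Tas and the direction turned in Pph (adjusted p = 0.782). With an estimated correlation 23 of the 42 list calls were kept and 19 lost; why was not tested. Of 419 pairs of a named gene and a comparison, 386 kept direction and call under each alternative that tested them, 33 lost the call under at least 1 and 0 reversed; a mean of at least 5 CPM covered 226 pairs, fits of 6 libraries 405 and leaving out chromosomes 8, 16 and 19 covered 364. Other scalings moved the median of all genes by at most 0.062 on the log2 scale. Replicate numbers did not pair the libraries: residual correlations of the 18 same-numbered pairs ran from -0.220 to 0.0861, and a block for the number gave 10303 genes in MP8. The pseudocount alternative did not apply to counts. Depth limits genes at 3 counts or fewer in each library of a group, whose folds are not given.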

Other observations

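The tests by chromosome, by gene span and by gene family were chosen only after the values were seen. The 1019 listed olfactory receptor genes, 36 of them tested, summed to 35.2 ± 0.646 CPM in WT, 114 ± 6.70 in MP8, 78.6 ± 1.72 in Tas and 59.7 ± 1.47 in Pph, with 28, 25 and 13 genes called higher and 1, 1 and 0 lower by edgeR; near-identical copies make single receptors uncertain. The gamma protocadherin cluster summed to 89.5 ± 0.755 CPM in WT, 150 ± 3.45 in MP8, 105 ± 1.49 in Tas and 129 ± 0.322 in Pph, with 15, 7 and 15 of 22 genes called higher and 0, 3 and 2 lower. Rhox genes summed to 77.2 ± 5.22 CPM in WT and 41.8 ± 1.75, 42.6 ± 0.788 and 25.6 ± 1.74 CPM in MP8, Tas and Pph, most of it from Rhox5. The Erdr1 and Mid1 genes together went from 203 ± 15.3 CPM in WT to 8.68 ± 1.48 in Tas, and stood at 163 ± 6.56 in MP8 and 217 ± 7.38 in Pph.

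Protein-coding genes that rose 2-fold or more were long. Their median span was 51.4 kb in MP8, 61.7 kb in Tas and 44.4 kb in Pph, against 20.6, 21.5 and 20.6 kb in draws of other genes of like level (permutation p = 1e-04 for each, the smallest that 10000 draws can give). Level here was the mean over the 12 libraries, so rising genes that were low in WT could be matched with genes of higher WT level. The span of genes that fell was not compared. Genes of chromosome 16 were higher in MP8, with a median log2 fold change of 0.24, and in Pph, with 0.20 (camera with an estimated correlation, adjusted p = 0.0011 for both), while Tas had a median of 0.10 (adjusted p = 0.261). In 4 equal parts of chromosome 16 in gene order, the medians in Tas were 0.175, 0.172, 0.195 and -0.348, against 0.225, 0.200, 0.263 and 0.281 in MP8 and 0.137, 0.146, 0.305 and 0.223 in Pph, so the first 3 parts were higher in Tas too and the last was lower. Compared directly, MP8 and Pph differed on chromosome 16 by a median of 0.020 (camera with an estimated correlation, adjusted p = 0.557). With 1 set of WT libraries, a lower level in WT cannot be told apart from rises in the null groups. The authors' deposited adjusted p-values called 8462 genes in MP8, 6664 in Tas and 7511 in Pph, of which 8231, 6537 and 7364 were also called here, all in the same direction.

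Genes of chromosome 19 were higher in Tas than in WT, with a median log2 fold change of 0.26. The shift was present in 1 null group of 3, which argues against an effect of losing the complex whichever subunit is lost. Extra copies of the whole chromosome in part of the Tas cells are consistent with the medians of 4 equal parts of the chromosome in gene order, the lowest of which was 0.197, and an effect of Tasor itself or of the clone stays open, since the labels name no clones. On chromosome 8 the 4 parts had medians of 0.293, 0.454, 0.451 and -0.139 in gene order, and the last argues against extra copies of that whole chromosome but leaves a gain of part of it open.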
